A study of Mus musculus with 1000 samples.

How the data were processed

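The study screened brain RNA from mice carrying mutations induced by N-ethyl-N-nitrosourea (ENU), a chemical mutagen that introduces mostly single-base changes. Per the labels' protocols, C57BL/6NCrl founder males received 3 ENU doses of 100 mg/kg, and their descendants were bred until induced mutations could become homozygous in generation 3. Animals of that generation were usually 8 to 12 weeks old, and the number of siblings usually screened in a pedigree was 12. The cerebellum was discarded and the remaining brain was kept in RNAlater, for at most 5 days, before RNA extraction.

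Per the labels' protocols, sequencing libraries were made with SMART-Seq v4 3′ DE chemistry, which captures the 3′ end of polyadenylated transcripts. A batch held 1152 RNA samples on 12 plates of 96 wells. Each sample contributed 4 ng of total RNA, which was reverse transcribed and amplified for 8 cycles with an in-line index that was unique within its plate row. The 12 cDNAs of a row were then combined into 1 pool, and 400 pg of each pool entered Nextera XT library preparation. All siblings in a row therefore shared every step after pooling. The submitters' processing notes name the aligner GSNAP and the mouse genome build GRCm38. How reads were counted, filtered and normalised is not given in the sources used here.

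The only processed table used here was a lookup, as deposited by the authors, that pairs each library name with the name of 1 of 3 processed files. It holds names and no read counts, expression values or sequencing depths. The expression files to which it points were not used here, so gene expression, inflammation states and depth per library were not analysed. Of its 23231 entries, 22231 belong to other libraries and were left out, apart from being counted and searched for names that match the libraries studied here.

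Each library was assigned to a mouse line from its title. The parts of the title were read as a line number, the mouse's number within the line, the plate, the well and the cDNA pool number. A line was read as a pedigree because the protocol describes sets of siblings, although no label states the equivalence. Lookup entries were matched to titles by exact text. Lines were counted per pool and per plate. The number of independent line contrasts that remain with plate or pool as a term was taken as the rank of the combined indicator matrix minus the rank of the plate or pool indicators. A line was called full at 12 libraries, with minimums of 10 and 6 as alternatives. These choices were made before the data were examined. The exceptions are the ranks, the counts of line pairs and sibling pairs, and the counts of serial numbers, which were added afterwards. The check of pool numbers against plate rows and the search for gaps between wells were not among the planned results. Nor were the lookup positions and the range and median of mouse numbers. The rule for named lines was fixed before the data were examined. It took lines with fewer than 12 libraries at either end of the accession range and those split over pools or plates. The lines that share a pool, and the remaining lines with fewer than 12 libraries, were named after their layout was seen. Planned tests of expression between lines and within fixed gene lists need expression values and were not run, so no gene is named. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.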

Results

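The data collected comprised 1000 RNA libraries, each from the brain of a different generation 3 mouse, in 88 lines descended from ENU-treated C57BL/6NCrl males. The screen was designed to find animals with abnormal inflammation states in the brain and then to look for causal variants by exome sequencing. No untreated or unmutagenised group was labelled among these libraries. The comparisons that these libraries allow are therefore between a line and other lines, and between siblings of the same line. Expression values were not analysed here. The results below therefore describe the composition of the lines and which of these comparisons can be separated from the steps of library preparation.

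Most lines were represented by the number of siblings that the protocol calls usual, which need not be all the mice of a line. Of the 88 lines, 79 had 12 mice each, 7 had 6 mice and 2 had 5 mice. The 2 smallest in this set were ENU57022, with mice numbered between 13 and 19, and ENU58180, with mice numbered between 1 and 16. These were the first and the last line in accession order, so their counts may cover only part of each line's libraries. The lines with 6 mice were ENU57173, ENU57263, ENU57268, ENU57406, ENU57441, ENU57466 and ENU58064. No mouse had more than 1 library and no well was used more than once, so each value measured on these libraries would have 1 library per animal, with siblings as the only biological replication within a line.

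The libraries came from 12 plates, labelled neuro2196 to neuro2207, and from 84 cDNA pools. The protocol gives 96 cDNA pools in a batch, so these are not all the pools of one. Whole rows, such as row G of neuro2197 and row A of neuro2198, held no library of this set. What those rows held was not analysed here. Plates held between 53 and 96 of these libraries and between 5 and 9 of these lines. All 96 wells were occupied by these libraries on 5 plates. The number read from the title as the pool counted along the plate rows for all 84 pools. A pool so read was the same set of libraries as a plate row. Of the 84 pools, 82 held 12 of these libraries. The incomplete ones were pool 68 on plate neuro2204, with 11 libraries, and pool 89 on plate neuro2207, with 5.

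For the comparison between lines, every one of the 88 lines lay on a single plate and in a single pool. A pool contained only 1 line in 80 of the 84 cases and 2 lines in the other 4. The 4 shared pools paired ENU57406 with ENU58064 on plate neuro2196, ENU57441 with ENU57263 on plate neuro2197, ENU57466 with ENU57268 on plate neuro2199, and ENU57173 with ENU57022 on plate neuro2204. Together they held 47 libraries. In each of them the first-named line occupied well columns 1 to 6, and the second began at column 7 or, for ENU57022, at column 8.

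**Figure D1:**
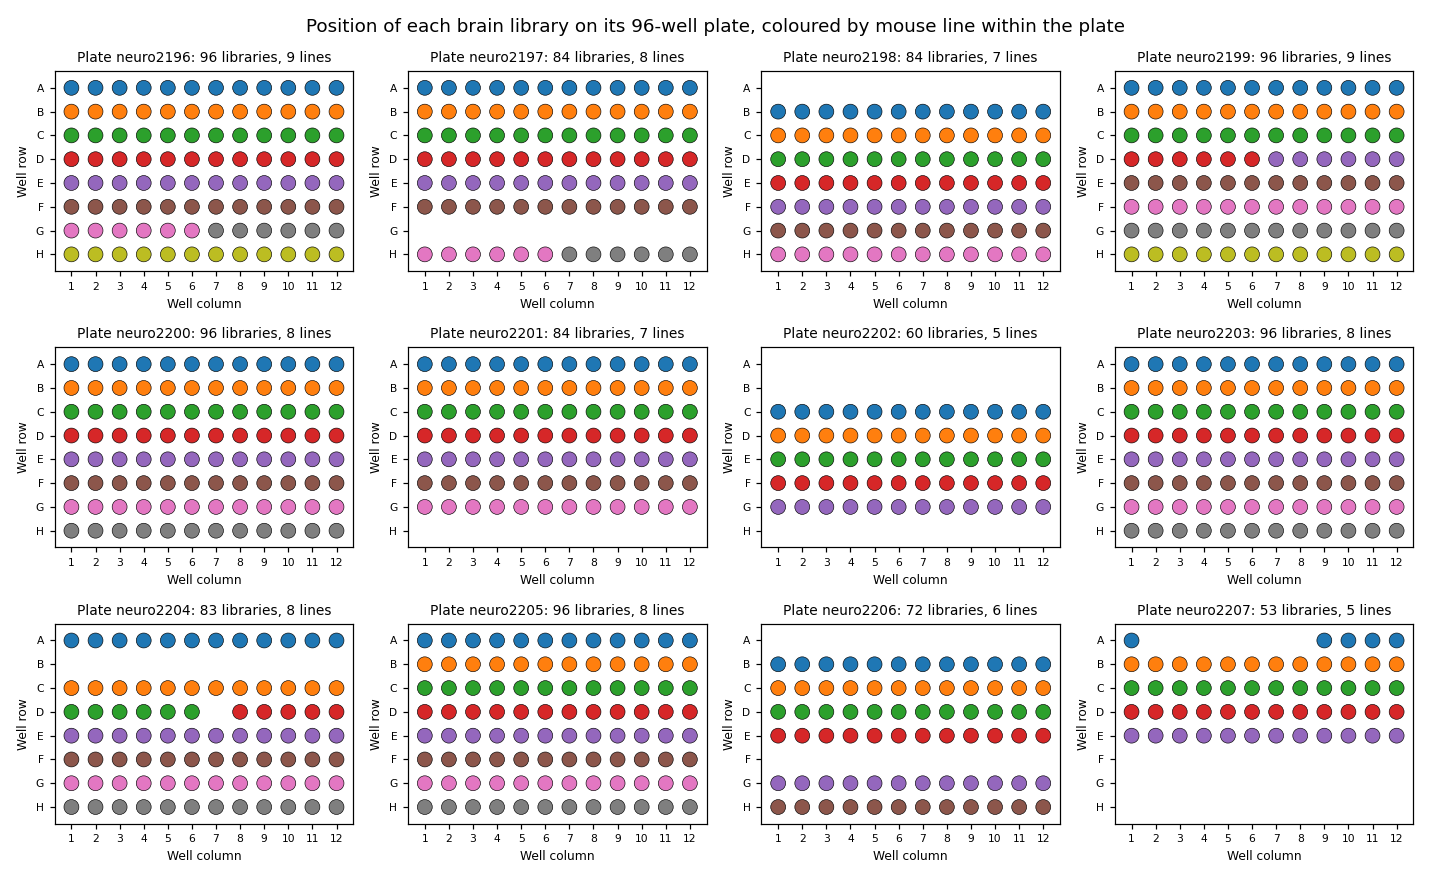
Position of each library on the 12 plates, with the well column on the horizontal axis and the well row on the vertical axis. Each point is 1 library, its colour marks the mouse line within that plate (colours are reused between plates), and blank positions are wells without a library in this set. Rows are of a single colour except the 4 rows that hold 2 lines.

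The 88 lines form 3828 pairs. Of these pairs, 289 (7.55%) shared a plate and 4 (0.104%) shared a pool. Without a technical term, 87 independent contrasts between lines can be estimated. With plate as a term 76 remained, and with pool as a term 4 remained, 1 for each shared pool. For the 80 lines that had a pool to themselves, and for the 8 others outside their own pool, a difference from another line cannot be told apart from a difference between pools in these libraries.

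For the comparison between siblings, all 5339 pairs of mice from the same line were in the same pool. A contrast between siblings, such as carriers against non-carriers of a segregating mutation, can therefore be made within a pool. Such a contrast is not free of the steps before pooling. These include storage in RNAlater, RNA extraction, reverse transcription, amplification and indexing of each sample. The age and storage time of each mouse were not analysed here. Neighbouring siblings were mostly in numerical order. Among 912 pairs of siblings next to each other in a row's well order, the mouse number rose with well column in 874 (95.8%). This share counts steps between neighbours, so a whole block placed out of order can lower it by only 1 step. In ENU58139, for example, mice 4 and 8 to 12 were in columns 1 to 6, and mice 1 to 3 in columns 7 to 9. A contrast between siblings that follows mouse number can therefore also follow well column, to an extent not measured for each line. Mouse numbers ranged from 1 to 35, with a median of 9.

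All 1000 library names were found in the lookup table, and all were assigned to the processed file numbered 3 of the 3 that it names. A comparison among these libraries thus involves no difference between processed files.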

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

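The number of full lines changed with the lowest minimum, and the order of siblings changed when numbers were compared as text. The alternatives for matching names and for pools and plates could not have changed their results. All 1000 libraries were found whether names were matched exactly, without regard to case and suffix, or by the line, mouse and well alone. The number of processed files named for the exact matches was 1, with file names compared as written or, necessarily, without regard to case and white space. The number of full lines was 79 at a minimum of 10 libraries, as at 12, and 86 at a minimum of 6. All 88 lines lay in 1 pool when pools were defined by plate and row, and so did all 86 lines with at least 6 libraries, which also each lay on 1 plate. The share of neighbouring siblings with a rising mouse number was 87.3% when numbers were compared as text, against 95.8% as whole numbers. That change follows from the construction of the alternative, since text order places 10 before 2. No paired analysis was possible because the table used here holds no measurement, and a mouse number shared between lines only names an animal within each line. For the same reason the tests of expression set out beforehand, with their other settings (count model, normalisation, filter on low counts, scale, permutation within plates and leaving out libraries), were not run. Sequencing depth was not analysed here, so nothing can be said of the precision of any expression value.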

Other observations

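The serial numbers that end the library names spanned 1152 consecutive values, equal to the batch size in the protocol, and 152 of them were not used by these libraries. The lookup entries of the 1000 libraries were a single run, from position 21001 to position 22000. The lines at both ends of the accession order, ENU57022 and ENU58180, were the only ones with 5 mice. Both lay in the only 2 rows with gaps between their wells, where column 7 of row D on plate neuro2204 and columns 2 to 8 of row A on plate neuro2207 held no library of this set. Whether further siblings of these 2 lines exist in other libraries was not analysed here, and the number of mice per line in this set should not be read as litter size for any line.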
